A study of Mediterraneibacter gnavus with 7 samples.

How the data were processed

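Total RNA was sequenced from cultures of Ruminococcus gnavus ATCC 29149 grown without oxygen in tryptic soy broth. Per the labels, exponentially growing cultures received pregnenolone or its ethanol vehicle for 1 h, ribosomal RNA was depleted, and stranded libraries were read on a Illumina NextSeq. There were 5 vehicle and 2 pregnenolone libraries. Groups were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical.

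The deposited files hold whole-number read counts per annotated feature, 1 library per file, not normalized. Per the file headers, the authors counted reads with featureCounts version 2.0.1, per feature rather than per gene, in the reverse-stranded setting and with multi-mapped reads counted at each of their places. Per the submitters' processing notes, BWA was used. Its version is not given in the sources used here. The features lie on 43 contigs named for the build R_gnavus-1.0.1, and coordinates below are 1-based positions on those contigs. Each file lists 3971 features, of which 129 had 0 counts in every library. The length of 98.8% of them is a multiple of 3, so these are coding lengths.

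The counting limits what can be said of single features. Because multi-mapped reads were counted at each place, features with a near-identical copy cannot be told from that copy. A feature was treated as repeated where it had at least 10000 counts and another feature of the same length matched its counts within 10% in every library, or where it lay in a series of 3 neighbouring features whose lengths recur elsewhere, and 51 features met this. This definition was set after the data were seen, in place of a looser one that had been looked at first. Separately, 1411 features overlap a neighbour on the same strand, and their counts are uncertain where they overlap. None of the genes named in the text was among the repeated features. Antisense overlaps are separated by the stranded counting.

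The pregnenolone group was compared with the vehicle group with the quasi-likelihood F test of edgeR version 4.0.16 in R version 4.3.3, with group as the only term, TMM scaling, the default expression filter and Benjamini-Hochberg adjustment at 0.05. The filter removed 794 features and left 3177, called genes below. CPM are counts per M (mega, as in the totals below) of TMM-scaled library size. A log2 fold change is pregnenolone over vehicle, and its standard error is the size of the log2 fold change divided by the square root of the F statistic, an approximation. The root of the common dispersion (biological coefficient of variation) was 12.1%. Total counts per library ran from 6.3 to 11.2 M counts. The level that a count of 0 allows, 3 counts, came to between 0.249 and 0.333 CPM in the vehicle libraries and to 0.669 and 0.539 CPM in the pregnenolone libraries. For genes with few counts, the ratio of summed counts has an exact binomial 95% interval. Such intervals and floors cover counting error only.

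The following choices were made before the data were examined: the test, the gene lists, the rule for named genes and most of the alternatives. The files do not pair the feature identifiers with gene names or products, and no reference annotation was used here. So of the planned lists, those defined by words in product descriptions were not used, and 2 lists given by identifier were. The first holds RUMGNA_00694 and RUMGNA_02133, published as hydroxysteroid dehydrogenases that act on bile acids. The second holds the 11 genes RUMGNA_02691 to RUMGNA_02701, published as the sialic acid (nan) cluster. The second was tested with camera from limma version 3.58.1 at the preset correlation of 0.01, with camera at an estimated correlation and with fry. The first was below the minimum of 5 members for a test. By the rule for genes without a product name, the text names the 2 genes with the largest change in each direction among those past the threshold whose pregnenolone values both lay outside the vehicle range, and in addition the members of the lists. Other features are described by their coordinates. The plan was to leave ribosomal and transfer RNA out of the library sizes. No name marks them here, so nothing was left out, and the fit that keeps them, listed beforehand, equals the reported fit.

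A run was defined as 3 or more features next to each other on 1 strand, all past the threshold in the same direction, and the number of runs was set beside 100 shuffles of the results over the features. Which runs are described, the limit of 1% of the counts of any library for abundant features left out of a fit, the limits of 1% and 0.1% of the vehicle counts for those described, the limit of 600 nt for short ones and the rule for segments were set after the data were seen. A segment joins genes changed in 1 direction that lie at most 3 features apart, with at least 20 tested genes and at least 70% of them changed that way. Library similarity was described with principal components and Spearman correlation of log2 CPM with a prior count of 2. Differences of library measures were tested with exact permutation tests over the 21 arrangements of the 7 libraries, two-sided.

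Alternatives were DESeq2 size factors, library size without TMM, no filter, a filter of 10 CPM in at least 2 libraries, DESeq2 version 1.42.0, limma-voom, a test against a fold of 1.5 with glmTreat, the replicate number as a block, the number in the name of each deposited file (1 or 3, meaning not stated) as a covariate or as a restriction, and each replicate left out. Added after seeing the data were a fit without the repeated, odd-length and abundant features (100 features) and a fit with only those vehicle libraries that carry the number 3. The test was also run on simulated data for the comparison of pregnenolone with vehicle. With 3163 genes in the simulated fit it recovered 52% of genes changed 1.5-fold and 77% of those changed 2-fold, and 5.84% of its calls were unchanged genes. Only 100 genes per fold were changed, as many up as down, and no shift of counts toward a few features was built in. In the data 55.3% of the tested genes were called and such a shift was present, so this false share cannot be carried over to them. In 20 simulated lists of 11 genes, camera called 20 of 20 when the genes moved 2-fold and 1 of 20 when they did not. The genes of these lists varied independently, while the correlation estimated for the sialic acid cluster was 0.8. So the rate of 1 in 20 cannot be carried over to the cluster.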

Results

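The effect of 1 h of pregnenolone on the transcriptome of Ruminococcus gnavus ATCC 29149 was measured by stranded RNA sequencing. R. gnavus is an anaerobic bacterium of the human gut, and pregnenolone is the steroid from which other steroid hormones are made. The comparison was between 5 vehicle (ethanol) libraries and 2 pregnenolone libraries. The labels give no dose. The vehicle libraries held 11.2, 7.93, 9.5, 8.22 and 8.79 M counts (replicates 1 to 5; M for mega) and the pregnenolone libraries 6.3 and 6.99 M. The means were 9.14 ± 1.32 M (SD, n = 5) and 6.65 ± 0.485 M (SD, n = 2), and all vehicle totals lay above both pregnenolone totals (exact permutation p = 0.095, two-sided, the smallest that 21 arrangements allow).

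The libraries separated by treatment. The first principal component held 78% of the variance, with the pregnenolone libraries at 33.8 and 35 and the vehicle libraries between -16.5 and -8.33. The vehicle library nearest to the pregnenolone libraries on this axis was replicate 1. Spearman correlations of log2 CPM across genes were 0.991 to 0.998 between vehicle libraries, 0.994 between the pregnenolone libraries, and 0.948 to 0.963 between the groups. As a check for a library deposited more than once, the counts of each pair of replicates were compared by chi-square. The chi-square per degree of freedom was 13.3 to 99.8 for the vehicle pairs and 68.4 for the pregnenolone pair, so no pair had the counts that repeated sampling of 1 library gives, where only counting error is considered.

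Many of the tested genes differed between the groups. Of 3177 tested genes, 856 were higher and 900 lower with pregnenolone, together 55.3% (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). This share depended on the fit: 1782 of 3842 genes were called with no filter, and 996 of 3177 with the replicate number as a block. Against a fold of 1.5, 593 of 3177 were called. Under TMM scaling, large changes were mostly increases. By at least 2-fold, 349 genes were higher and 213 lower, and by at least 4-fold, 82 were higher and 14 lower. Changes of this size were not counted under the other scalings. In 2014 genes (63.4%) the values of the groups did not overlap, where chance gives 9.5%. The balance of higher and lower genes rested on the scaling. With library size only, 356 genes were higher and 1938 lower, the median log2 fold change of all genes shifted by -0.57, and 50 genes were called in the direction opposite to the TMM result. A number in the names of the deposited files, of unstated meaning, was 1 for both pregnenolone libraries and for vehicle replicates 3 and 5. Within these 4 libraries 872 genes were higher and 876 lower. The number 3 occurred on vehicle libraries alone, so no comparison within it exists.

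**Figure D1:**
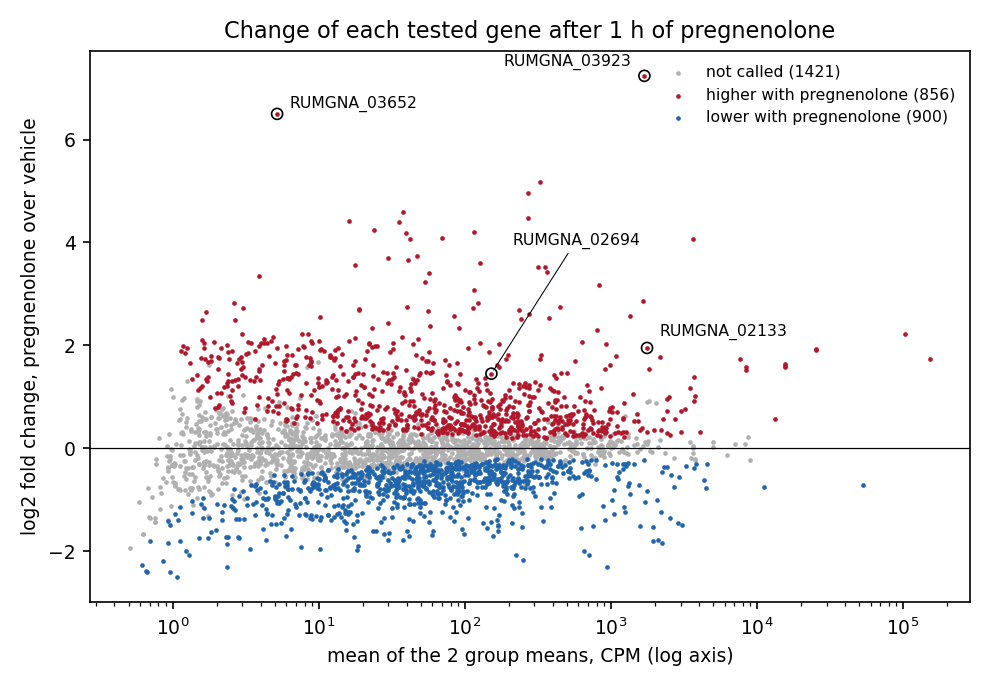
Each point is 1 of the 3177 tested genes, with the mean of the 2 group means in CPM on a log axis and the log2 fold change of pregnenolone over vehicle on the other axis, under TMM scaling. Red marks the 856 genes higher and blue the 900 genes lower with pregnenolone, and circles mark RUMGNA_03923 at 7.24, RUMGNA_03652 at 6.50, RUMGNA_02133 at 1.95 and RUMGNA_02694 at 1.45.

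The strongest response was that of RUMGNA_03923, a 1323-nt coding feature at 3532 to 4854 on the plus strand of contig 44.2. Its level rose from 21.7 ± 20.6 CPM (SD, n = 5) to 3370 ± 330 CPM (SD, n = 2), a log2 fold change of 7.24 (SE 0.57) or 152-fold (edgeR adjusted p = 5.09e-06). Vehicle replicate 1 had 57.8 CPM and the other vehicle libraries 9.99 to 19.5 CPM, and without replicate 1 the log2 fold change was 8.05. RUMGNA_03652, a 288-nt feature at 158652 to 158939 on contig 378, was almost silent in vehicle. It had 5 counts over all vehicle libraries and 100 over the pregnenolone libraries, a ratio of 102 with an exact binomial 95% interval of 42 to 320 (edgeR adjusted p = 3.66e-06). Of these 5 counts, 3 were in vehicle replicate 1. The fitted log2 fold change of 6.50, which depends on the prior count, was 7.27 without that library and 7.30 within the 4 libraries numbered 1. The files do not pair these identifiers with gene names.

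The 2 genes named for the largest decreases were near the detection limit. Not all genes at least 4-fold lower were: a feature at 368658 to 369398 on contig 252 fell from 1560 ± 86.1 to 317 ± 12.2 CPM (log2 fold change -2.30). RUMGNA_02401, at 67167 to 68174 on contig 103, had 90 counts over the vehicle libraries and 3 over the pregnenolone libraries, a ratio of 0.169 (exact binomial 95% interval 0.034 to 0.511, edgeR adjusted p = 0.0202). All 3 were in pregnenolone replicate 1. Replicate 2 had 0, which set against a floor of 3 counts is at least 3.34-fold lower than vehicle. The fitted log2 fold change of -2.51 was -1.39 without replicate 2 and -7.08 without replicate 1, the latter against a library at 0 and no bound. RUMGNA_01003, at 74602 to 75909 on contig 244, had 57 and 2 counts, a ratio of 0.178 (interval 0.021 to 0.674, edgeR adjusted p = 0.00472). Neither passed without pregnenolone replicate 2, where the log2 fold change of RUMGNA_01003 went from -2.41 to -2.26. RUMGNA_02401 also did not pass with the file-name number as a covariate (edgeR adjusted p = 0.06) or against a fold of 1.5 (glmTreat adjusted p = 0.068). RUMGNA_01003 did not pass in DESeq2 (adjusted p = 0.059).

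Both genes of the steroid list were higher with pregnenolone, also when adjusted over the list alone (2 of 2). RUMGNA_02133, published as a hydroxysteroid dehydrogenase acting on bile acids, lies at 90796 to 91548 on contig 46. It rose from 726 ± 246 CPM (SD, n = 5) to 2810 ± 268 CPM (SD, n = 2), 3.86-fold, with a log2 fold change of 1.95 (SE 0.26, edgeR adjusted p = 0.000128). RUMGNA_00694, published as another bile acid hydroxysteroid dehydrogenase, lies at 18411 to 19241 on contig 31. It rose from 47.1 ± 3.36 to 71.9 ± 11.9 CPM, a log2 fold change of 0.61 (SE 0.12) or 1.53-fold (edgeR adjusted p = 0.00141). Its change rested on the scaling: with library size only its log2 fold change was 0.05 (edgeR adjusted p = 0.75), and that of RUMGNA_02133 was 1.39. RUMGNA_00694 also missed the threshold in a test against a fold of 1.5 (adjusted p = 0.53, over its alternatives 1.8e-05 to 0.75).

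Most genes of the sialic acid cluster were higher with pregnenolone. The cluster lies at 135157 to 146811 on the minus strand of contig 169 and is known to take up and break down sialic acid released from mucin. Of its 11 genes 10 were higher and none lower with pregnenolone over all genes tested, and 11 of 11 were higher adjusted over the list alone. The median log2 fold change was 1.45 (2.73-fold), with a range of 0.73 to 1.76. The sialidase RUMGNA_02694 rose from 81.4 ± 22.3 CPM (SD, n = 5) to 223 ± 17.7 CPM (SD, n = 2), with a log2 fold change of 1.45 (SE 0.20, edgeR adjusted p = 0.000183). RUMGNA_02699 did not pass, at 12.5 ± 3.69 and 20.7 ± 8.12 CPM (log2 fold change 0.73, edgeR adjusted p = 0.0501). With library size only the median was 0.88, and 10 genes were again called higher.

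As a set, the cluster was higher than other genes by camera (p = 7e-05), but not with an estimated correlation (p = 0.22 with an estimated correlation, which was 0.8). By fry, which does not compare with other genes, p was 0.0021. The mean log2 CPM of the cluster was 4.45 ± 0.39 in vehicle (SD, n = 5) and 5.89 ± 0.07 with pregnenolone (SD, n = 2). Vehicle replicate 1 stood apart at 5.12, while the other vehicle libraries lay between 4.15 and 4.38. Without it the median log2 fold change was 1.70 and 11 genes were higher. Without pregnenolone replicate 2, RUMGNA_02701 no longer passed (edgeR adjusted p = 0.068).

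**Figure D2:**
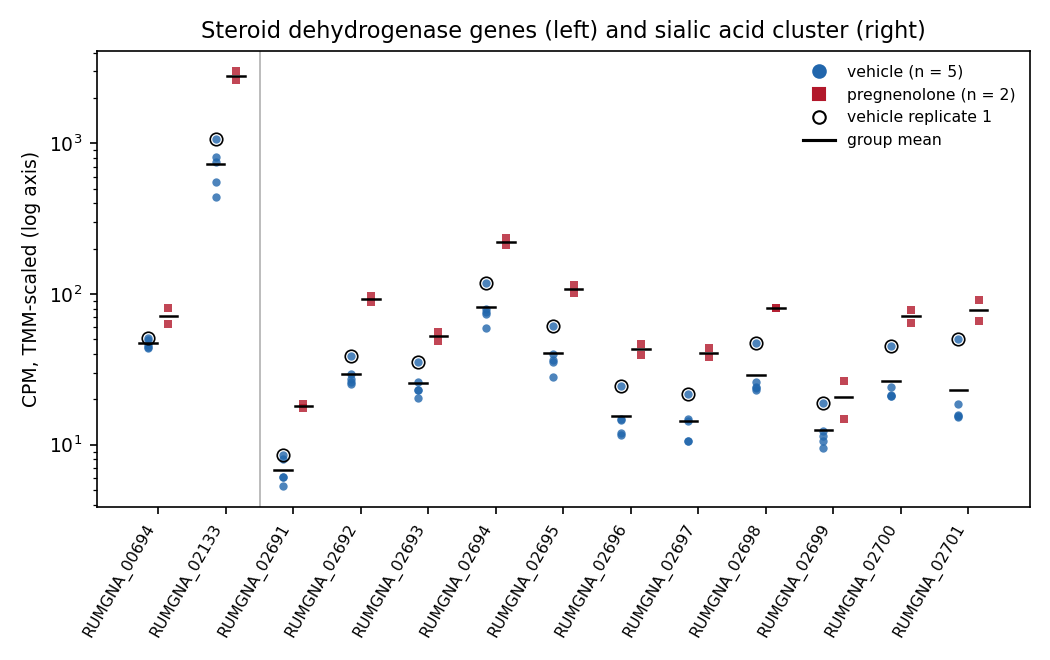
Each point is the level of a gene in 1 library in TMM-scaled CPM on a log axis, blue for the 5 vehicle and red for the 2 pregnenolone libraries, with group means as black bars and vehicle replicate 1 circled. RUMGNA_00694 and RUMGNA_02133 are left of the line and the 11 genes of the sialic acid cluster right of it, where the pregnenolone values lie above all vehicle values except in RUMGNA_02699.

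Changed genes lay next to each other along the genome. There were 78 runs of 3 or more neighbouring features higher with pregnenolone, holding 351 features (41% of those called higher), and 104 runs of lower features, holding 503 (55.9% of those called lower). In 100 shuffles of these results the medians were 29 and 32 runs and the highest numbers 43 and 44. No shuffles were run for the alternative fits, which called other numbers of genes. Their numbers of runs, given next, therefore cannot be set beside the shuffled ones. With library size only there were 31 higher and 229 lower runs, and against a fold of 1.5 there were 32 and 13. Without pregnenolone replicate 1 or 2 there were 64 or 59 lower runs.

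The strongest 3 of the higher runs rose at least 16.6-fold at the median. On contig 30, 3 features at 58155 to 62490 on the minus strand had a median log2 fold change of 4.48, and their summed level rose from 103 ± 14.5 CPM (SD, n = 5) to 1820 ± 119 CPM (SD, n = 2). On contig 202, 7 features at 41536 to 48252 on the plus strand had a median of 4.25 and rose from 38.1 ± 12 to 875 ± 18.6 CPM. On contig 378, 5 features at 172979 to 176298 on the minus strand had a median of 4.06 and rose from 496 ± 158 to 7930 ± 172 CPM. Further runs lay on contig 16.1 at 45443 to 47705 (3 features, median 3.40), on contig 376 at 12965 to 19327 (6 features, median 3.03) and on contig 3.1 at 1077 to 6816 (6 features, median 2.74). The run on contig 376 was uneven, with members from 0.43 to 4.41, and its summed level rose only from 1020 ± 101 to 1760 ± 64.2 CPM. The medians of these 6 runs were above 0 under each scaling, though 1 member of the run on contig 376 changed sign with library size only.

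Among the lower runs, 13 features on contig 252 at 365592 to 376866 on the plus strand fell in summed level from 28600 ± 1500 CPM (SD, n = 5) to 10200 ± 660 CPM (SD, n = 2), with a median log2 fold change of -1.53. On contig 3.1, 22 features at 63003 to 88481 on the minus strand fell from 5590 ± 183 to 2340 ± 24.7 CPM, with a median of -1.37. On contig 246, 11 features at 27200 to 32933 on the minus strand had a median of -1.61 and fell from 406 ± 40.4 to 179 ± 11.5 CPM. The lowest medians were those of 6 features at 128027 to 135225 on contig 252 (-1.76) and of 3 features at 36474 to 39794 on contig 30 (-1.72).

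**Figure D3:**
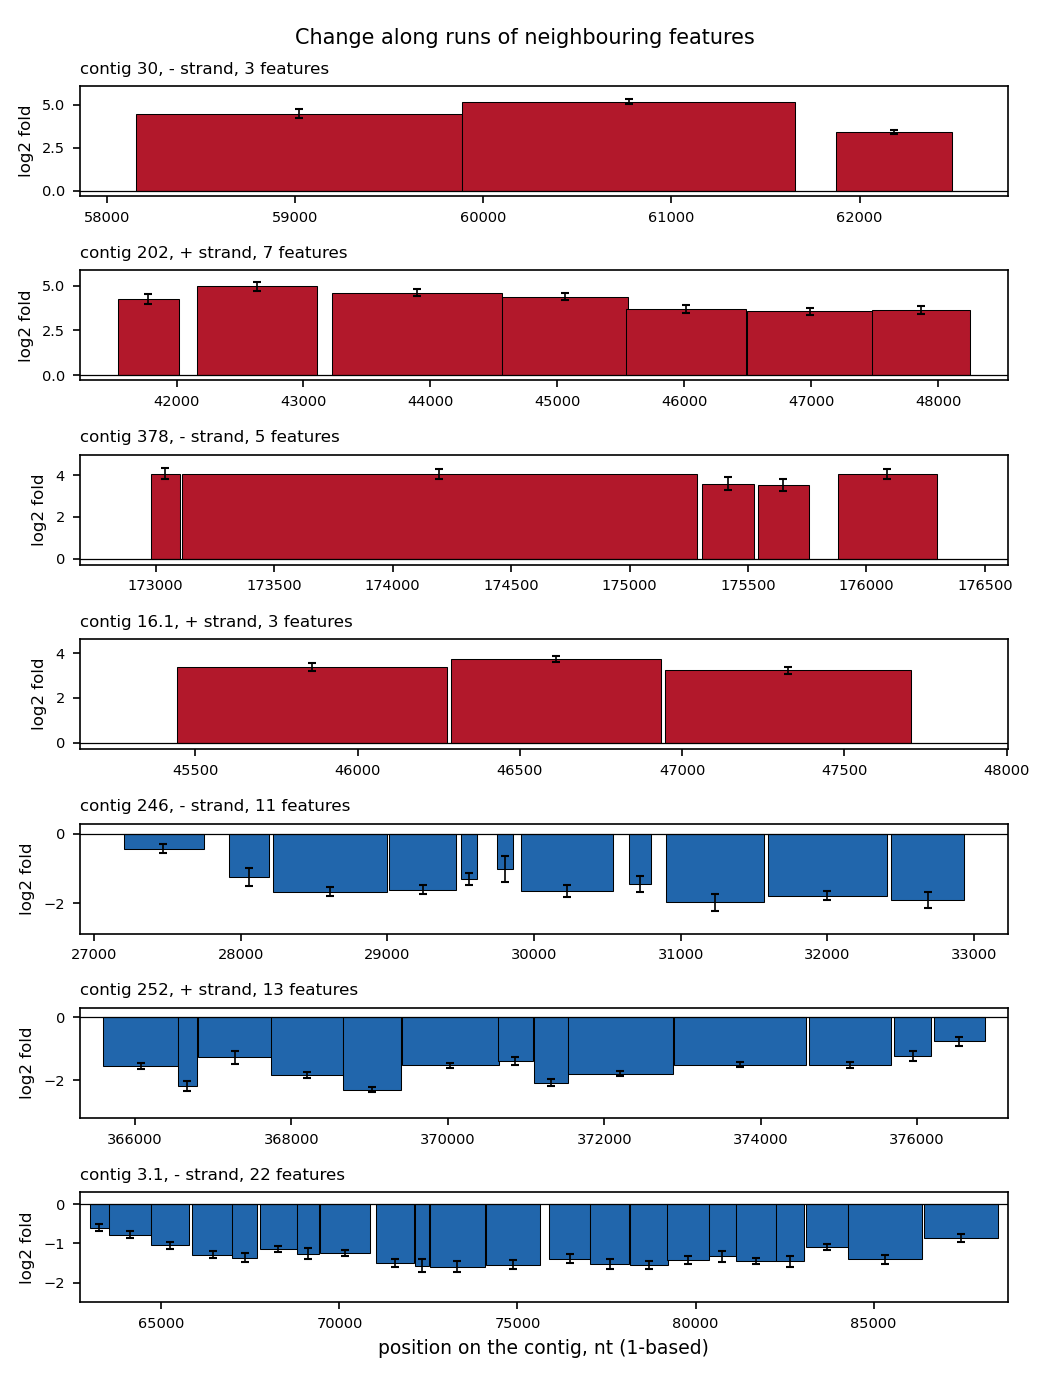
Each box is a feature at its position on the contig in nt, and its height is the log2 fold change of pregnenolone over vehicle with the standard error as a bar. The upper 4 panels show runs higher with pregnenolone, with medians of 4.48, 4.25, 4.06 and 3.40, and the lower 3 panels show lower runs, with medians of -1.61, -1.53 and -1.37.

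A few features took a larger share of the counts in the pregnenolone libraries. The 8 features above 1% of the vehicle counts on average held 25.5 ± 1.34% of the vehicle counts (SD, n = 5) and 41.7 ± 3.82% of the pregnenolone counts (SD, n = 2). Of these, 4 were shorter than 600 nt and all 4 were higher with pregnenolone, with a median log2 fold change of 1.91 (1.33 with library size only). They took 14.3 ± 1.53% and 36.3 ± 4.05% of the counts, and 2 of them have a near-identical copy. These 2, both of 267 nt, lie at 17516 to 17782 on contig 327 and at 86523 to 86789 on contig 357. They matched each other, at 1.19% and 1.18% of the vehicle counts and at 2.98% each of the pregnenolone counts. So they cannot be told apart, and the shares above may count the same reads at both. Of the 4 short features, 1 without a copy was a 342-nt feature at 1839 to 2180 on contig 244. It went from 7.89 ± 1.51% to 17.7 ± 1.23%. Another without a copy, a 162-nt feature at 353 to 514 on contig 363, went from 4.05 ± 0.842% to 12.7 ± 3.69%. A 2622-nt feature at 110524 to 113145 on contig 169 went the other way, from 7.36 ± 0.35% to 3.02 ± 0.0285%, with a log2 fold change of -0.71. Short features with lower levels were mixed: of the 43 above 0.1% of the vehicle counts, these 4 included, 24 were higher and 8 lower, with a median log2 fold change of 0.57 that became -0.01 with library size only. These shares enter the library sizes, and the TMM factors were 1.07 to 1.14 in the vehicle libraries and 0.712 and 0.796 in the pregnenolone libraries. Other library measures also separated the groups, each at exact permutation p = 0.095. Repeated features held 5.73 ± 1.57% of the vehicle counts (SD, n = 5) and 12.2 ± 3.1% of the pregnenolone counts (SD, n = 2). Features whose length is not a multiple of 3 held 1.93 ± 0.608% and 3.61 ± 1.06%. Features at 0 numbered 316 ± 17.9 and 398 ± 30.4. Whether ribosomal or transfer RNA is among the abundant features could not be told, since no name marks it.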

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

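Both tests reported in this part were chosen after the values had been seen, and they replaced a first version over all genes at least 4-fold higher that decided nothing. Of 34 reported values, 9 had a vehicle library far from the others by Dixon's test, which chance gives in about 1 in 20, and in 8 of the 9 the library was vehicle replicate 1. These values are not independent, since several come from 1 cluster. Over all 3177 tested genes, vehicle replicate 1 was far from the others in 151 and the other vehicle libraries in 15 to 37 each.

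Vehicle replicate 1 had 57.8 CPM of RUMGNA_03923 where the other vehicle libraries had 9.99 to 19.5. In the sialic acid cluster it had 24.4 CPM of RUMGNA_02696 (others 11.6 to 14.7), 47.4 of RUMGNA_02698 (23.1 to 26), 45.2 of RUMGNA_02700 (21 to 24) and 50.6 of RUMGNA_02701 (15.2 to 18.5). Its mean log2 CPM over the cluster was 5.12 (4.15 to 4.38). The run on contig 202 from 41536 summed to 58.7 CPM in it (29.2 to 37.7), and the run on contig 3.1 from 1077 to 260 CPM (105 to 120). The remaining value was in vehicle replicate 4, with 2.93 CPM of RUMGNA_02401 (1.41 to 1.78).

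These values in vehicle replicate 1 lay toward the pregnenolone libraries, and it was the highest vehicle library in 51 of the 82 genes at least 4-fold higher with pregnenolone. Among the 213 genes at least 2-fold lower the shift was less clear, since it was the lowest in 60 and the others in 17 to 49. Carry-over of pregnenolone RNA or reads would add 1 constant share of the pregnenolone excess to every gene, and RUMGNA_03923 limits that share to 1.34%. The excess in the sialic acid cluster would need a median share of 37.8% (quartiles 31.8 and 44.3), which argues against carry-over as the whole cause there. Among the 82 genes, 20 lay above a bound of 2 times that share by more than 3 SD of the other vehicle libraries, but vehicle replicate 4 had 11 by the same count. So for these 82 genes as a set, carry-over and other differences of vehicle replicate 1 cannot be told apart. The labels name nothing that sets vehicle replicate 1 apart, and no biological explanation was tested.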

How the results depend on the processing

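The fit without repeated, odd-length and abundant features and the fit with only vehicle libraries numbered 3 were chosen after seeing the data. The fit that keeps ribosomal and transfer RNA, listed beforehand, was not run apart, since without product names it equals the reported fit. With library size only, 356 genes were higher and 1938 lower, with 31 and 229 runs, because every fold change shifts by about -0.57. Against a fold of 1.5, 377 genes were higher and 216 lower, with 32 and 13 runs, a stricter hypothesis by construction. The camera test of the sialic acid cluster gave p = 0.22 with an estimated correlation. By fry (limma), which does not compare with other genes, p was 0.0021. Without 1 replicate at a time, 663 to 920 genes were higher and 635 to 897 lower, with 54 to 86 higher and 59 to 109 lower runs, and camera gave 7.3e-11 to 2e-04. Lower runs numbered 64 without pregnenolone replicate 1 and 59 without replicate 2. In these fits the lone pregnenolone sample is assumed to vary like the vehicle samples. Apart from these and the replicate block, the counts of genes and runs lay within 1.5 times those reported in each alternative.

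With the replicate number as a block, 541 genes were higher and 455 lower, with 49 and 45 runs, and RUMGNA_00694, RUMGNA_01003, RUMGNA_02401 and RUMGNA_02701 did not pass (edgeR adjusted p of 0.078, 0.062, 0.087 and 0.057). Only 2 numbers occur in both groups, and the samples share only a number. The deviations of same-numbered samples from their group means correlated at -0.14 and -0.22. With 2 pregnenolone samples, the deviations of 1 are those of the other with the sign turned. So these are not separate checks, and they do not settle whether the numbers pair samples. Of the values of named genes under all alternatives, 300 kept direction and side of the threshold, 12 no longer passed, 7 newly passed (all RUMGNA_02699), and no direction reversed. The cause of the lost calls was not tested. The genes named as lower had few counts, 90 and 57 over the vehicle libraries.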

Other observations

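The test of neighbouring genes, the rule for segments and the test of abundant features were chosen after seeing the data, as was leaving those features out before thinning. The other tests of why so many genes changed were set before their results were known.

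Some long stretches of the genome held mostly genes changed in 1 direction. On contig 13.1, all 25 tested genes between 71290 and 95324 were higher with pregnenolone, with a median log2 fold change of 1.90 (quartiles 1.78 and 2.02). On contig 46, 23 of 25 tested genes between 40846 and 65360 were higher (median 1.82), and on contig 103, 21 of 23 between 1249 and 16266 (median 1.35). Their baseline was low, with a median vehicle level of 3.68, 1.54 and 9.13 CPM against 43 CPM over all tested genes. On contig 246, 24 of 26 tested genes between 27200 and 41800 were lower (median -1.30), from a median vehicle level of 27.4 CPM. This stretch includes the run of 11 features from 27200 described above. With library size only the higher stretches had medians of 1.34, 1.26 and 0.79, with 0, 3 and 1 genes changing sign. What these stretches encode was not analysed here.

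Genes next to each other may have changed together because they are transcribed together. Across genes, which are not independent replicates, log2 fold changes of neighbours on the same strand correlated with a Spearman rho of 0.666 (2312 pairs) and those of neighbours on opposite strands with 0.0825 (364 pairs). The difference was larger than in all of 10000 permutations of the strand relation (p = 1e-04, one-sided, the smallest they can give). The permutations did not match pairs by their gap, and opposite-strand pairs were not split by gap. So this p-value cannot separate strand from distance. The rho was 0.771 for 963 same-strand pairs with a gap of 0 to 50 nt and 0.29 for 131 pairs with a gap over 200 nt. This is consistent with shared transcription, as a hypothesis; transcripts themselves were not mapped.

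In the test of chance for the change of 55.3% of the tested genes, of the 21 splits of the 7 libraries into 5 and 2, only 1, the real one with 1756 genes, gave as many, which is the smallest share 21 splits allow, and the highest of the others gave 0 (edgeR, with up to 147 genes at an unadjusted p under 0.05; no other tool was run on them), though each of the others mixes the groups, so that the real difference widens their spread. The libraries that share the file-name number 1 alone gave 1748 genes, which argues against a difference between the numbers as the main cause. Between vehicle libraries numbered 3 (n = 3) and 1 (n = 2), 2 of 3159 genes were called. With 448 genes at an unadjusted edgeR p under 0.05 there, a smaller difference between the numbers remains open. A few abundant features that took reads from all others would lower the rest alike, so the question for higher genes is the scaling that corrects this. With library size only, 335 of 3104 genes outside the abundant, repeated and odd-length features were still higher. So these calls do not rest on the choice between TMM and library size only. Over all tested genes, 856 were higher with TMM and 356 with library size only, so the other higher calls do rest on it. Outside the abundant, repeated and odd-length features, 1909 genes were lower with library size only. Among all tested genes, 1938 were lower with library size only and 900 with TMM, so the other lower calls rest on that choice too. With TMM and without the abundant, repeated and odd-length features, 836 genes were lower. These calls remained after the correction by TMM. How complete that correction is was not tested. With every library thinned to 2.79 M reads outside the abundant, repeated and odd-length features, 1588 genes were called. This argues against the lower depth of the pregnenolone libraries as the whole cause. A difference in culture or harvest that goes with the pregnenolone group remains open beside the treatment, since the labels do not record either.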
